A study of Homo sapiens
Mus musculus with 6 samples.

How the data were processed

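Gene expression was measured in MCF7 xenograft tumours on single-colour oligonucleotide arrays for human genes. MCF7 is an established human breast carcinoma cell line that depends on estrogen for growth. Per the labels' protocols, total RNA came from stabilised tumour tissue, the RNA of the 10 tumours grown from 1 cell clone was pooled in equal amounts, and digoxigenin-labelled cRNA was made from each pool and hybridised to 1 array. The clone is therefore the replicate, with 3 control clones (empty vector, clones 4, 9 and 25) and 3 clones that carry human podoplanin (clones 6, 11 and 14). Groups and clone numbers were taken from the sample titles. Each array stands for 5 mice, and the spread between mice or tumours of a clone was averaged out by the pooling and cannot be read from these data.

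The authors deposited, for each array, a raw spot intensity, a signal-to-noise score and a spot flag for 32878 probes, per the file headers. The intensity is linear and had already been corrected for background, since 20 to 31 spots per array had values at or below 0. The scanner and its software are not given in the sources used here. The authors also deposited a table of normalised intensity for the whole series. Its columns rank the probes as the raw intensity does (Spearman correlation 1 on each array), share 1 maximum, and are empty exactly where the raw intensity was not above 0, which identifies them as quantile normalised values on a linear scale. The submitters' processing notes name R 2.3.1 and no method.

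For the main analysis, the raw intensities above 0 were quantile normalised between the 6 arrays and log2 transformed with limma 3.58.1 in R 4.3.3. No further background correction was applied. The result differed from the log2 of the deposited table by at most 0.0179 at any tested probe. Spots with a flag of 5000 or more (65 to 164 per array) were treated as failed and left out. This limit was adopted here because the file does not explain its flag codes. A probe was called detected on an array at a signal-to-noise score of at least 3, and was tested if detected on at least 3 of the 6 arrays, whichever group these belonged to. This left 21441 probes (65.2%) of 19111 genes. Where several probes shared a gene identifier without its version, the gene was counted by its brightest tested probe over all 6 arrays.

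Podoplanin and control tumours were compared with limma's moderated test (lmFit and eBayes), with no covariate, and Benjamini-Hochberg adjustment over all tested probes at a threshold of 0.05. Log2 differences are podoplanin minus control throughout, and errors are the moderated standard errors unless an SD is named. Single genes were also compared by a two-sided exact permutation test of the 3 against 3 arrays, which cannot give a p below 0.1. The test was tried on simulated data for 21423 probes with the spread of the real arrays and 200 probes changed by known folds. It called 46.3% of the 2-fold, 74.6% of the 4-fold and 87.9% of the 16-fold changes at an adjusted p of 0.05, with 5 false calls. Where no array of a group detected a probe, its fold was taken against the higher of the probe's own signal and the lowest signal among detected probes on each array. For every probe given so below, this equalled the estimated fold. Such a fold is therefore an estimate that rests on signal below detection, not a lower limit. The number of arrays limits the precision, and the between-array spread covers clone, pool, labelling and hybridisation together.

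The files identify 32396 of the 32878 probes by a Celera gene number (hCG followed by digits) and pair none of them with a gene symbol. Symbols were assigned through a RefSeq gene table (GRCh38.p14), 129 probes by RefSeq transcript accession without version and 13 by a Celera number listed as a synonym of a gene. The other 32736 probes are unnamed here. This gave 129 named genes, of which 78 genes (86 probes) were tested, and no probe had more than 1 symbol. The array's genome build is not given in the sources used here, so no coordinates are printed. Many of the named genes belong to families with near-identical copies, and their probes may read more than 1 copy.

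The rule for genes named in the text was fixed before the data were examined. It took PDPN, 3 genes of prior interest to the study (EDN1, VIL1, TNC), up to 10 named genes in each direction whose groups of clones do not overlap (those past the threshold first, then by the smallest p), and 3 members of each of 27 gene lists. The lists, with 728 genes for actin and Rho regulation, junctions, matrix, vessel growth factors, estrogen response, proliferation, host cell types, RNA handling and others, were to be tested with camera. None of the 728 list genes and none of PDPN, EDN1, VIL1 and TNC were among the 129 named genes. The gene list tests, the check of the labels by PDPN and the markers of host cells were therefore not analysed here, nor were the settings planned for them. The fixed rule held no clause for unnamed probes. As an addition to it, the 2 unnamed probes with the smallest p in each direction are given by their Celera number. Other genes described outside this rule are said to have been chosen after their values were seen.

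The alternatives tried were median and 75th percentile scaling, the deposited table as starting values, an offset added to the signal (the median signal of undetected spots, 609), no filter, detection on all 6 arrays, eBayes with a trend and robust prior, array weights, the mean of a gene's probes, and leaving out each clone in turn with the tested probes kept. Cyclic loess normalisation was added after the data were seen. No scan date or slide is given in the files, so no batch term was fitted. Figures were drawn with matplotlib 3.10.9.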

Results

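The data comprised 6 arrays of MCF7 tumours grown in the mammary fat pads of nude mice. MCF7 clones had been stably transfected with a tetracycline-regulated vector that was empty or carried the cDNA of human podoplanin, a mucin-like membrane glycoprotein known as a marker of lymphatic endothelium and found at the invasive edge of some carcinomas. Each clone was injected on both sides into 5 mice bearing a pellet with 0.72 mg of estradiol for release over 60 days. Tumours were removed after 24 days, and the RNA of 10 tumours per clone was pooled. The groups held 3 control clones and 3 podoplanin clones, with 1 array per clone. The comparison between the groups asks which human transcripts of the tumour differ when the cancer cells overexpress podoplanin.

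The arrays were of similar quality. Between 20768 probes (63.2%, podoplanin clone 11) and 21749 probes (66.2%, control clone 4) of 32878 were detected at a signal-to-noise score of at least 3. The median raw signal lay between 3696 (podoplanin clone 6) and 5795 (control clone 9). Over the tested probes, log2 signals correlated at 0.987 to 0.989 between control clones, at 0.970 to 0.981 between podoplanin clones and at 0.964 to 0.987 between groups. The control clones resembled one another more closely than the podoplanin clones did. Between 591 and 815 probes differed at least 2-fold between any pair of control clones, against 1155 to 2031 between any pair of podoplanin clones.

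Podoplanin clone 14 stood apart from the other 5. On its array 1667 tested probes (7.78%) lay at least 2-fold from the mean of the other arrays, 619 above and 1048 below. The corresponding number was 773 (3.61%) for podoplanin clone 6, 552 (2.58%) for podoplanin clone 11, and 398 to 673 for the control clones. The first principal component, with 41.6% of the variance, set clone 14 (score 69.3) against scores of -28.3 to 0.54 for the other arrays. On it, podoplanin clones 6 and 11 (scores -2.03 and 0.54) also lay above the control clones (scores of -16.2 or less). The second component, with 20.8%, separated podoplanin clone 6 from the other arrays. Among named genes, TCAF1, a regulator of TRP ion channels, had a log2 signal of 10.2 in clone 14 against a mean of 11.8 over the others, and LCE1D, a late cornified envelope gene, had 12.4 against 11.4. Both were chosen after their values were seen.

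**Figure D1:**
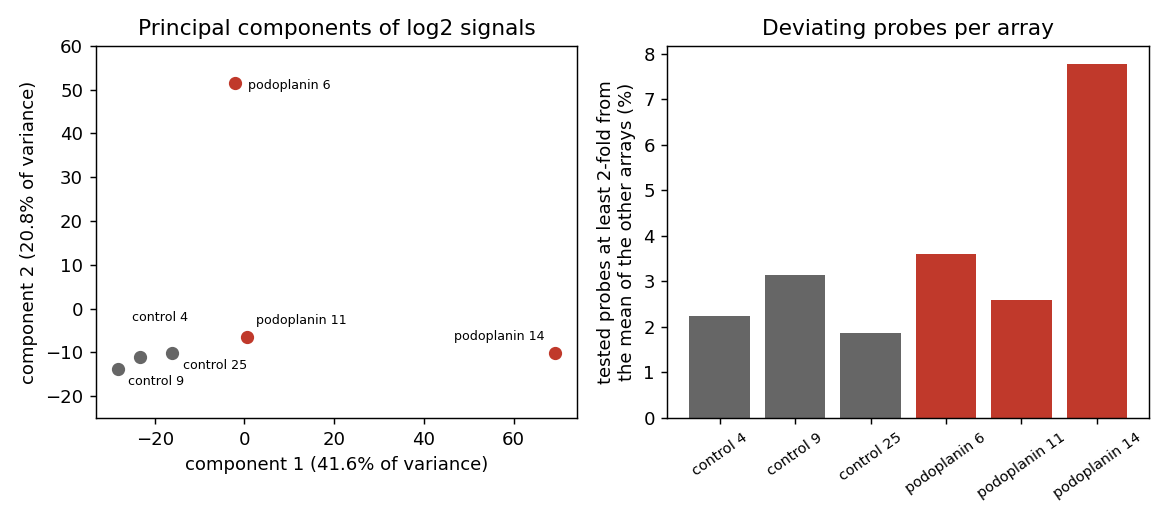
Left, scores of the 6 arrays on the first and second principal components of the log2 signals of tested probes, with grey points for control and red points for podoplanin clones. Right, the share of tested probes (%) on each array at least 2-fold from the mean of the other 5 arrays, which reached 7.78% for podoplanin clone 14 and at most 3.61% for any other clone.

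Between podoplanin and control tumours, 1 gene passed the threshold. The probe of Celera gene hCG15341.4 rose from a log2 signal of 8.91 ± 0.159 (SD, n = 3) in control tumours to 20.04 ± 0.547 (SD, n = 3) in podoplanin tumours. Its signal-to-noise score was 1.19 to 1.95 on the control arrays, which is below detection, and 92.5 to 154 on the podoplanin arrays. The signal was an estimated 2250-fold higher in podoplanin tumours (log2 difference 11.14, SE 0.278, limma adjusted p = 0.000145, higher in all 3 clones). This fold rests on control signal below detection and is not a lower limit. The raw signal was 545442 in clone 6, 1466999 in clone 11 and 1290948 in clone 14, against 403 to 540 in the controls. The symbol of this gene is not given by the tables used here. PDPN itself has no named probe among them, so the level of the transfected gene was not analysed here and the group labels were not checked by it.

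No other gene passed an adjusted p of 0.05 in limma, and none passed in the downward direction, where 780 had an unadjusted p of at most 0.05. These counts depended on the settings: 2 lower genes passed without podoplanin clone 11 and 1 without podoplanin clone 6, and a trend and robust prior gave 3 higher genes. The next largest rise was 3.97 and the largest fall -3.20 on the log2 scale, neither past the threshold. The second smallest p belonged to hCG37265.3, with a log2 signal of 9.00 ± 0.150 (SD, n = 3) in control and 10.5 ± 0.147 (SD, n = 3) in podoplanin tumours. It was detected on no control array and on all 3 podoplanin arrays, an estimated 2.88-fold higher, with limma adjusted p = 0.163. The smallest p among lower genes belonged to hCG38616.2 and hCG16580.2, which were detected on all 3 control arrays and on no podoplanin array. The first had an estimated 6.52-fold more signal in control tumours (log2 difference -2.70, SE 0.288, limma adjusted p = 0.207) and the second 2.62-fold more (log2 difference -1.39, SE 0.155, limma adjusted p = 0.231). With the offset added to the signal, their log2 differences were -1.77 and -0.94.

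At an unadjusted p of 0.05, 1737 of 19111 genes (9.09%) differed, where 956 would be reached with no difference at all. Of these, 957 had higher and 780 lower signals in podoplanin tumours, a share of 55.1% higher that became 71.0% under median scaling and 48.3% under 75th percentile scaling, so that the split had no settled direction. At an unadjusted p of 0.01 and at least 2-fold, 96 genes had higher and 56 lower signals. This imbalance was absent without podoplanin clone 14, with 73 higher and 74 lower. The lower genes numbered 34 without control clone 4, 94 without podoplanin clone 6, 109 without podoplanin clone 11, 90 with no filter and 24 with detection required on all 6 arrays. The groups of clones did not overlap for 3132 genes (16.4%), against a chance share of 10%. The number of genes at an unadjusted p of 0.05 was 1142 without control clone 4, 1140 without control clone 9, 1432 without control clone 25 and 1372 without podoplanin clone 14, and it was 2018 without podoplanin clone 6 and 2044 without podoplanin clone 11. The median log2 difference over all genes was -0.00922 and the median size of a difference 0.155, close to the median standard error of 0.161. Probes switched between detected and not detected in both directions. Detection on all 3 control arrays and no podoplanin array was seen for 79 probes, and the reverse for 47, while other groupings of 3 against 3 arrays gave 28 to 86.

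**Figure D2:**
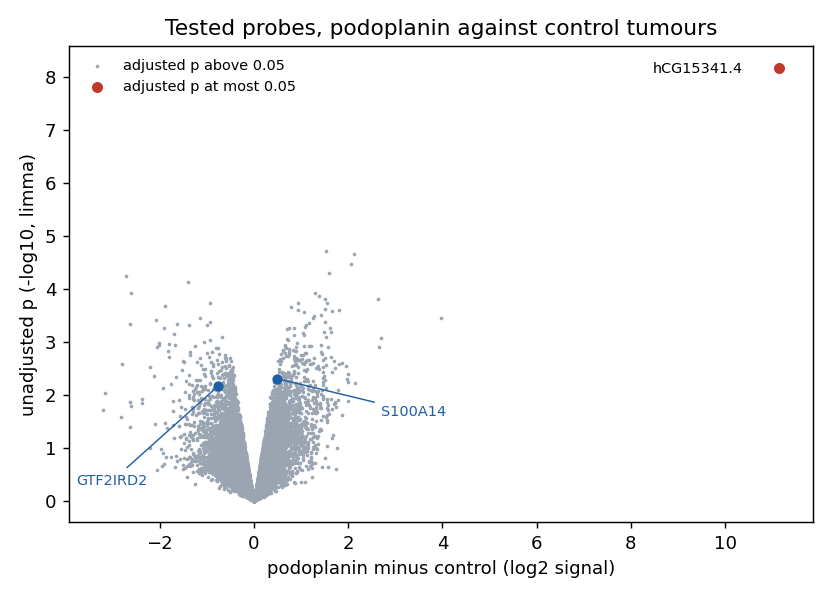
Each point is 1 of 21441 tested probes, with the log2 difference podoplanin minus control on the horizontal axis and the unadjusted limma p on a -log10 scale on the vertical axis (3 clones per group). The probe of hCG15341.4, in red, lies at 11.14 on the log2 scale, while the next largest rise is 3.97; S100A14 and GTF2IRD2, in blue, are the named genes with the smallest p.

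Of the 78 named and tested genes, 38 had a higher and 40 a lower mean in podoplanin tumours. None passed the threshold over all genes (limma, lowest adjusted p = 0.421), nor after adjustment over the named genes alone (lowest 0.274), and 3 had an unadjusted p of at most 0.05. The groups of clones did not overlap for 12 of the 78 genes (15.4%, chance 10%), 7 with higher and 5 with lower signals in podoplanin tumours. For each of these the exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. S100A14, an EF-hand calcium-binding protein of the S100 family expressed in epithelia, had the smallest p. Its log2 signal was 17.3 ± 0.114 (SD, n = 3) in control and 17.8 ± 0.102 (SD, n = 3) in podoplanin tumours, a 1.41-fold higher mean (log2 difference 0.50, SE 0.119, limma adjusted p = 0.421, 95% interval 0.21 to 0.79). GTF2IRD2, a transcription factor of the TFII-I family with a near-identical copy in the genome, had 13.5 ± 0.241 (SD, n = 3) in control and 12.7 ± 0.284 (SD, n = 3) in podoplanin tumours, 1.70-fold more signal in control tumours (log2 difference -0.77, SE 0.196, limma adjusted p = 0.441, 95% interval -1.24 to -0.29). It was detected on 2 of the 3 podoplanin arrays.

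The other named genes with separate groups differed by 1.30-fold or less, and none passed the threshold. Among those with higher means, RAC3, a Rho-family GTPase that acts on the actin cytoskeleton, had a log2 difference of 0.34 (SE 0.150), the histone gene H4C14 one of 0.26 (SE 0.113), and CENPX, a centromere protein also found in the Fanconi anaemia core complex, one of 0.22 (SE 0.105). FAM72D, a member of a family of near-identical copies, had 0.21 (SE 0.101), LCMT2, an enzyme of tRNA modification, 0.16 (SE 0.109), and SGF29, a chromatin reader of the SAGA complex, 0.09 (SE 0.106). Among those with lower means, ZDHHC11, of the palmitoyltransferase family, had a log2 difference of -0.33 (SE 0.141), the hair keratin-associated gene KRTAP23-1 one of -0.38 (SE 0.177), TMDD1 one of -0.22 (SE 0.132), and THOC3, a subunit of the THO complex for mRNA export, one of -0.16 (SE 0.109). Their limma adjusted p ranged upward from 0.562.

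**Figure D3:**
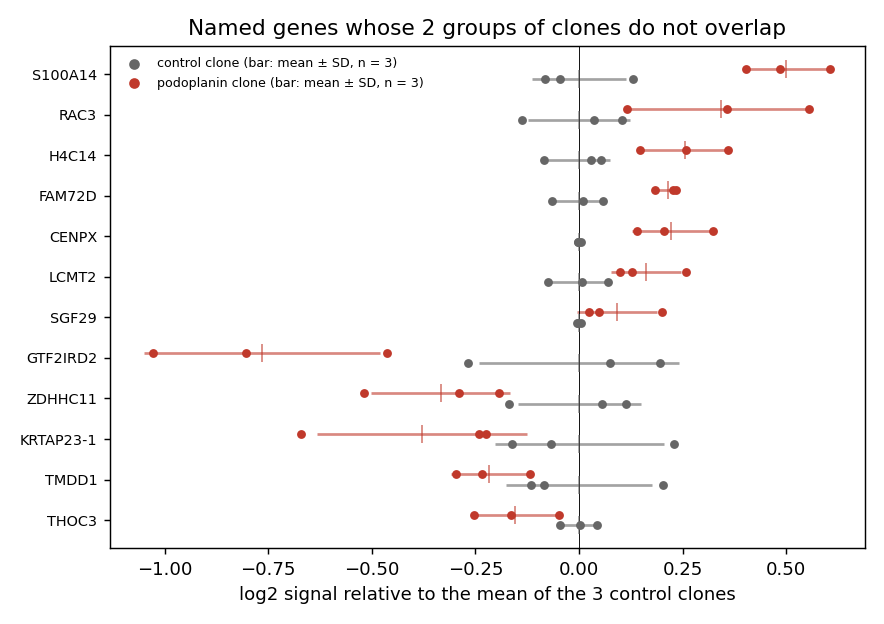
Log2 signal of each clone relative to the mean of the 3 control clones for the 12 named genes whose groups do not overlap, with grey points for control clones, red points for podoplanin clones, and bars for the mean and SD (n = 3). S100A14 has the largest difference upward (0.50) and GTF2IRD2 the largest downward (-0.77); no gene shown passed the adjusted threshold.

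Some further named genes are given with the interval of their difference; they form no fixed list and were chosen after their values were seen. ACTG1, cytoplasmic gamma-actin, had a log2 signal of 21.0 ± 0.089 (SD, n = 3) in control and 21.1 ± 0.081 (SD, n = 3) in podoplanin tumours (log2 difference 0.15, 95% interval -0.12 to 0.42). For WNT7B, a secreted Wnt ligand, the difference was 0.16 (95% interval -0.14 to 0.47). For the chemokine CXCL17 it was -0.03 (95% interval -0.44 to 0.38). MYL5, a myosin light chain, had -0.44 (95% interval -1.04 to 0.16). KLC2, a kinesin light chain detected on 1 control and 2 podoplanin arrays, had 0.46 (95% interval -0.79 to 1.71). The 2 probes of MMP23B, a membrane-bound matrix metalloproteinase with a near-identical copy, gave -0.09 (95% interval -1.11 to 0.92) and 0.36 (95% interval -0.14 to 0.85); the second was detected on only 2 control and 1 podoplanin arrays, so its interval does not bound the change in the transcript. The 3 probes of ANAPC1, the largest subunit of the anaphase-promoting complex, gave 0.04, 0.20 and 0.24, with standard errors of 0.13 each. These intervals exclude changes of 2-fold or more for ACTG1, WNT7B and CXCL17, while MYL5 and the first MMP23B probe remain open to a 2-fold fall. The interval of KLC2 reaches a 2-fold rise. With detection on only 1 control and 2 podoplanin arrays, it does not bound the change in that transcript in either direction.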

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

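No paired analysis was possible because the clone numbers of the groups are not shared and no other label pairs the samples. All 16 settings, of which only cyclic loess was chosen after the data were seen, kept the direction and side of the threshold of hCG15341.4 wherever its probe was tested (log2 difference 9.95 to 11.45, limma adjusted p 2.17e-06 to 0.00681). Detection on all 6 arrays removed this probe and left 0 genes past the limma threshold, with 1638 at an unadjusted p of 0.05. A trend and robust prior gave 3 genes, all higher in podoplanin tumours, and leaving out each clone in turn gave 1 to 3; genes with lower signal passed in 2 of the 16 settings, 2 genes without podoplanin clone 11 and 1 gene without podoplanin clone 6. The cause was not tested. The 16 genes followed through the settings (251 values) changed neither direction nor side of the threshold, but 9 values of 7 genes, none of them called, moved by more than 1.5 times. Median scaling took THOC3 from -0.16 to -0.03, SGF29 from 0.09 to 0.19, FAM72D from 0.21 to 0.33 and TMDD1 from -0.22 to -0.12. Leaving out podoplanin clone 14 took SGF29 to 0.04 and KRTAP23-1 from -0.38 to -0.23, and leaving out control clone 25 took TMDD1 to -0.12. The offset took hCG37265.3 from 1.53 to 0.89 and hCG38616.2 from -2.71 to -1.77. Genes lower at an unadjusted p of 0.01 and 2-fold numbered 90 with no filter and 24 with detection on all 6 arrays against 56, and 34 to 109 without each clone in turn. The higher ones numbered 73 to 134 without each clone in turn, against 96, and without podoplanin clone 14 both directions were about equal (73 and 74). Genes at an unadjusted p of 0.05 numbered 1140 to 2044 without each clone in turn. Median scaling moved the share of higher genes among these from 55.1% to 71.0%, and 75th percentile scaling gave 48.3%, so their split has no settled direction. The low number of called genes has to be read against the simulation, in which 46.3% of 2-fold changes were called with 3 arrays per group. Noise was independent between probes there, and 200 probes were changed at once, 67 of them by 4-fold and 66 by 16-fold. The Benjamini-Hochberg cut-off is less strict where many probes pass, and here 1 gene passed. For both reasons this share may be too high for the real arrays. Probes near the signal-to-noise limit carry little information on their change.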

Other observations

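Tests of failed spots and of detection on the array of clone 14, and of the transfected cDNA, were chosen after the results they bear on had been seen; the splits of the samples and the comparisons of probe pairs were set before. Among named genes, differences between single clones were larger than any between the groups. TLR1, a receptor of innate immunity, had a log2 signal of 13.4 in control clone 9, with a signal-to-noise score of 12.3, against a mean of 10.1 over the other 5 clones. AHNAK2, a large scaffold-type protein, had 12.5 in podoplanin clone 11, 11.8 in control clone 4 and 11.4 in control clone 25 but was not detected in control clone 9 (9.78), podoplanin clone 6 (9.12) or podoplanin clone 14 (10.1). These genes were chosen after their values were seen. TLR1 and AHNAK2 had 1 tested probe each and 1 array per clone, so their values have no check. Each was detected on only 3 of the 6 arrays. Keratin-associated hair proteins, a family on no fixed list, and the test of their joint variation were also chosen after the values were seen. Of 17 probes for them, 10 were tested, of which 4 had higher and 6 lower means in podoplanin tumours. Only 1 had an unadjusted p of at most 0.05, and none passed the limma threshold. That 1 had a higher mean in podoplanin tumours and was not KRTAP23-1, whose unadjusted limma p was 0.0735. Their signals varied together over the 6 arrays a little more than most lists of equal size and brightness (mean pairwise correlation 0.166, percentile 96.9 of 10000 random lists).

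The first pattern is the rise of hCG15341.4. Failed spots are argued against by its unflagged spots, its scores of 92.5 and above, and an SD of 0.547 (log2) over the podoplanin clones. One candidate source is the transfected cDNA itself, since all 3 control clones lacked detectable signal and all 3 podoplanin clones had it. The bounds set for that were a signal-to-noise score below 3 on control arrays and a signal in the top 1% on podoplanin arrays. All 3 control arrays met theirs. None of the podoplanin arrays did, since 1.18% to 2.69% of probes were brighter, so 3 of 6 arrays lay on the side set. The bound of 1% had no basis in the design, and with no gene name for the probe the transgene and an endogenous gene cannot be told apart. Among the 10 splits of the 6 arrays, the real one gave 1 gene at adjusted p and the highest other 0, and 10 splits are too few for a share under 0.05. Every other split mixes arrays with and without this signal in a group and so could not call this probe. The splits therefore add nothing on its rise.

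The second pattern is the excess of small p-values, 1737 genes where 956 would be reached by chance. The highest count in the other 9 splits was 1040, and at an unadjusted p of 0.01 with 2-fold the real split gave 152 genes against at most 57; the real split was the 1 with most genes both times, but 10 splits are too few for a share under 0.05. Noise of single spots as the whole cause is argued against by genes with a second probe, of which 95 of 134 (70.9%, exact 95% binomial interval 62.4 to 78.4) had differences of the same sign at both probes; in 45 of the 134 the second probe was also at an unadjusted p of 0.05 in that direction, and over all such genes the log2 differences of both probes correlated at 0.367 (across genes, which are not independent replicates). Intensity-dependent bias of the kind that cyclic loess removes is argued against, since 1.80 times the chance number remained after it. The count hardly moved, with 1718 genes against 1737 after quantile normalisation, which also acts on such bias. Bias that neither normalisation removes was not tested. What stays open, as untested, is podoplanin itself, other differences between the clones picked for each group, and host tissue in the tumours. Differences between the groups in RNA preparation, labelling or hybridisation were not tested either. Both probes of a gene were read on the same array from the same cRNA, so their agreement cannot exclude such differences.

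The third pattern is the distance of podoplanin clone 14. Weaker detection is argued against by its 64.4% of detected probes, inside the range of the other arrays. Noise of single spots as the whole cause of the probes at least 2-fold away is argued against by probe pairs. In 61 of 79 genes (77.2%, exact 95% binomial interval 66.4 to 85.9) the second probe lay on the same side. The share was lower only in podoplanin clone 11 (73.3%). It was 85.7% to 96.8% on the other arrays, from 9 to 31 pairs each, with 95% intervals that all overlapped that of clone 14. Whether noise has a larger part in clone 14 than there cannot be told from these shares. Over all 1897 genes with a second probe, the deviations on the array of clone 14 correlated at 0.338 (95% interval 0.297 to 0.377, across genes, which are not independent replicates). The lower limit was just short of the bound of 0.3 set for it, so a part of noise cannot be told apart there. On the other arrays the correlation lay between 0.231 (podoplanin clone 11) and 0.42 (podoplanin clone 6). A difference of this clone, of its pooled tumours or of the RNA preparation may each account for the rest, and 1 array per clone does not separate them.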
